A study of Arabidopsis thaliana with 60 samples.

How the data were processed

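Poly(A)+ RNA of the base of the Arabidopsis inflorescence stem was sequenced in 60 libraries, 8 from wild type (Columbia-0) and 4 from each of 13 lines with altered lignification. Per the labels' protocols, the segment from 0.5 to 2 cm above the stem base was taken from 28-day-old plants, 6 plants were pooled for each sample, tissue was frozen in liquid nitrogen at harvest, and libraries were made with a strand-specific TruSeq mRNA kit. The series' design text calls the samples of a group biological replicates. What separated them beyond pooling is not stated. A p-value here sets a difference against a spread shared by all groups. Their own median SD (log2) ran from 0.0776 (C4H:F5H) to 0.17 (wild type) and 0.174 (fah1). It can be too small for groups of wide spread.

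The values analysed are whole-number counts of reads per gene, deposited by the authors as one table of AGI loci by libraries. Per the submitters' processing notes, the tools used were Trimmomatic, HISAT2 2.1.0, HTSeq and DESeq2 1.22.2, with TAIR10 as the genome build. Those notes do not give the role or order of the tools. The gene annotation release, the read filters and whether HTSeq counted by strand are not given in the sources used here, so counts of genes that overlap a neighbour on the other strand cannot be assigned to a strand with certainty. Organelle genes took 0.01612 to 0.08933% of a library's counts. The table held 32833 genes, 4607 of them with no count in any library, and no entry that names no gene. A reference annotation of the TAIR10.1 assembly was used only for gene symbols, gene biotype and the order of neighbouring genes. It held 32548 of the loci; the other 285 took 0.03331% of all counts. Positions are given as AGI loci and chromosome numbers only.

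Genes were kept by edgeR's filterByExpr with the groups as design (minimum count 10, minimum total count 15), which left 21218. Library sizes were scaled with TMM factors. All 60 libraries were fitted in one model with a term for each of the 14 groups, so that every comparison shares one estimate of the spread, and differences were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with Benjamini-Hochberg adjustment over the genes tested. A gene is called changed at an adjusted p under 0.05. The common biological coefficient of variation was 13.82%. Levels are CPM after TMM scaling, as mean ± SD over the libraries of a group; fold changes are the model's log2 values with a standard error derived from the test statistic. Where a group had no read at all, the fold is a bound computed against 3 counts in each of its libraries, which covers counting error only. Counts were simulated with 200 of the 21218 genes changed between ref2 and wild type, besides the 22 jasmonate genes raised 2-fold. The test recovered 86.6% of the genes changed 1.5-fold (n = 67). It recovered 100% of those changed 2-fold (n = 67) or 4-fold (n = 66), and called 13 of 20996 unchanged genes. These rates were not tested on the real libraries, where wild-type replicates differ among themselves.

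Before the data were examined, 20 gene lists were fixed from textbook knowledge of the pathway, of stem tissue and of defence and stress responses, 5 of them markers of cell types the stem base holds (tracheary elements, green tissue, phloem, epidermis, cambium); 310 of the 317 listed genes were tested. Each list was tested in each of the 13 comparisons with wild type by camera (limma 3.58.1, two-sided, preset correlation 0.01), which compares a list's genes with all others, with adjustment over all 260 tests. The same tests were repeated with the correlation between a list's genes estimated from the data. A list that holds a line's own mutated gene was tested with it. The genes named in the report follow a rule also fixed in advance. It takes the genes of each line's lesion or transgene. It then takes, among protein-coding genes that have a symbol, a mean log2 CPM of at least 0, an adjusted p under 0.05 and no overlap of CPM between the groups, the 5 with the largest rise and the 5 with the largest fall (3 and 3 between mutants). Last come up to 3 changed members of each of the 4 lists with the smallest camera p. Genes named outside this rule are marked as such where they appear.

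Each line was compared with wild type; 5 further comparisons set lines against each other, and an interaction term asked whether med5a/b acts differently with and without ref2. Overlaps between comparisons that share the wild-type libraries are given beside simulated unchanged groups and with the wild type divided between the comparisons. Single scores were compared with exact permutation tests, two-sided. Alternatives fixed in advance were relative log expression factors in place of TMM, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, wild-type replicates 1 to 4 only, and leaving out each library in turn. The comparison of wild-type replicates 5 to 8 with 1 to 4, replicates 5 to 8 only, the gene lists without wild-type replicate 1 or 3 and the wild-type sets without each library were chosen after seeing the data. No library was left out of the reported fits. Among 106 pairs of libraries within groups, none agreed within sampling noise (chi-square per gene 5.322 to 194). The members of several families named here (RBCS, LHCB1, GSTU, UGT73B, COR15, VSP, KIN1 with COR6.6, IGMT and CYP79F1 with CYP79F2) are near-identical copies, and the split of reads between such copies is uncertain.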

Results

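RNA was sequenced from the base of the Arabidopsis thaliana inflorescence stem, which is depositing lignified secondary walls. The 60 libraries came from wild type (n = 8) and 13 lines with a lesion or transgene in lignin formation (n = 4 each). Library totals ran from 33127608 counts in cadc cadd replicate 4 to 92966829 in C4H:F5H replicate 3. Levels are CPM (mean ± SD) and log2 folds carry a standard error.

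Genes named by the labels were examined library by library. In pal1 pal2, which lacks the main isoforms of phenylalanine ammonia-lyase, PAL1 (AT2G37040) lay between 79.4 and 285 CPM against 958 to 2800 in wild type, and PAL2 (AT3G53260) between 74.3 and 148 against 416 to 802. 4CL1 (AT1G51680) lay between 33.1 and 49.5 CPM in 4cl1 and between 679 and 2030 in wild type, and CSE (AT1G52760) between 19.9 and 28.5 in cse-2 and between 330 and 732 in wild type. In cadc cadd, CAD5 (AT4G34230) had 6 reads over 4 libraries against 396 ± 110 CPM in wild type, and CAD4 (AT3G19450) lay between 17.1 and 20.9 against 81.6 to 164. F5H1 (AT4G36220) lay between 22.9 and 38.3 CPM in fah1 and 78 and 97.7 in ref8 fah1 SmF5H, against 164 to 780 in wild type, and between 24500 and 27100 in C4H:F5H, where the transgene's reads are counted with the gene. CYP83A1 (AT4G13770) lay between 378 and 433 CPM in ref2 and 500 and 606 in med5a/b ref2, against 1320 to 1840. The 3 lines with med5a/b mutations kept 24.8 to 32.5 CPM of MED5A (AT3G23590) as group means against 78.2 ± 6.33, and 9.95 to 11 of MED5B (AT2G48110) against 25.7 ± 2.67. In each of these cases no library of the line reached the wild-type range. The ref3 and ref8 alleles change the protein, and the level of C4H (AT2G30490) or C3H1 (AT2G40890) does not check those labels. C4H was higher than wild type in both ref3 lines, and C3H1 was 356 ± 38.7 CPM in ref8 fah1 SmF5H and 769 ± 36.9 in med5a/b ref8 against 447 ± 106.

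Wild-type replicates 5 to 8 differed from replicates 1 to 4 in 6425 genes when the 8 libraries were fitted alone. The count was 3704, 4002, 2953 and 3709 without replicates 1, 3, 6 and 7 and 8821 without replicate 2; the comparison and these fits were chosen after seeing the data. Replicate 2 lay between the sets. Its chi-square per gene was 24.57 and 25.09 with replicates 5 and 8, 47.91 and 68.37 with 7 and 6, and 38.26 to 63.32 with 1, 3 and 4. Mean scores over list genes were higher in replicates 5 to 8 for monolignol biosynthesis (0.4 ± 0.13 against −0.38 ± 0.32), secondary wall polysaccharides (0.48 ± 0.02 against 0.02 ± 0.19) and secondary wall transcription factors (0.47 ± 0.09 against −0.05 ± 0.19). They were lower for epidermis and cuticle markers (−0.22 ± 0.15 against 0.65 ± 0.37), photosynthesis (−0.05 ± 0.26 against 0.4 ± 0.1) and lignin polymerisation (−0.24 ± 0.07 against 0 ± 0.04), on a log2 scale with n = 4 each. Each of these 6 differences had an exact permutation p of 0.0286, the smallest that 70 splits of 8 libraries allow, and an adjusted p of 0.0636 over the 20 lists. Of 113 list calls, 69 passed against either set, 15 against replicates 1 to 4 alone, 28 against 5 to 8 alone and 1 against neither.

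**Figure D1:**
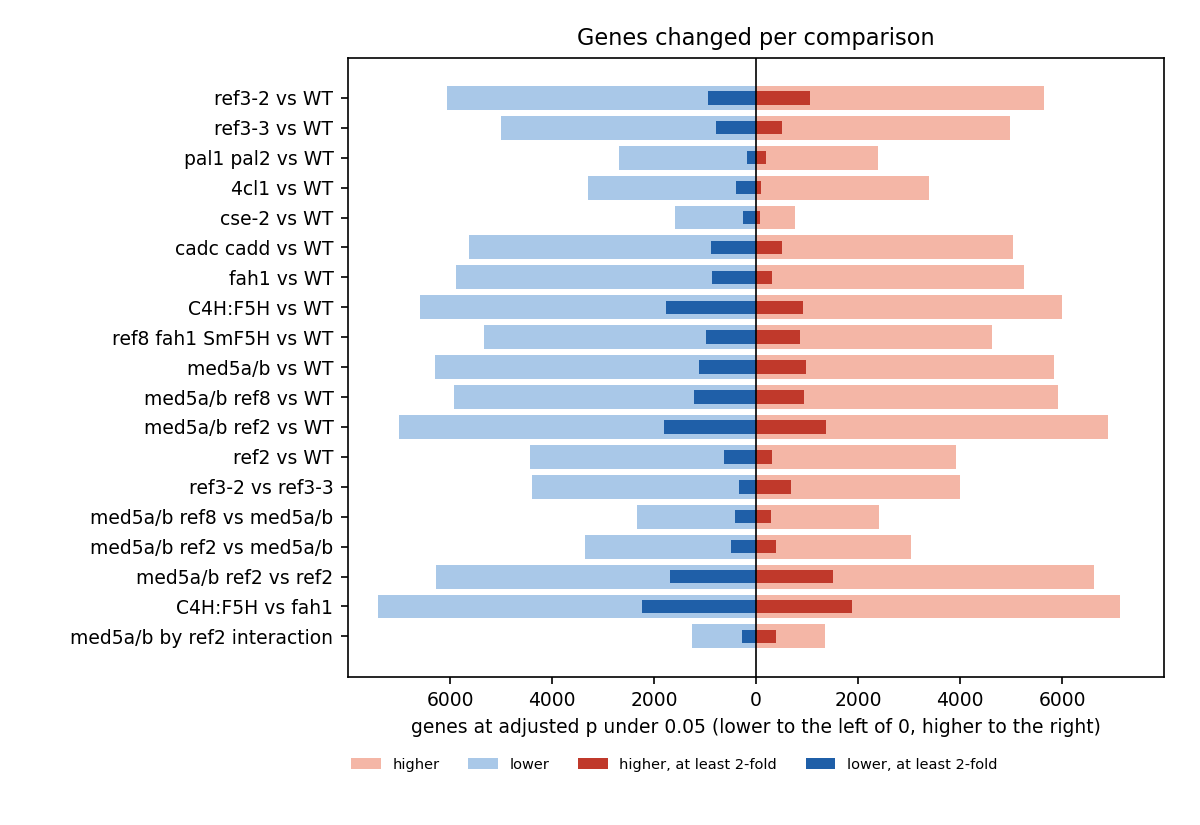
Number of genes at an adjusted p under 0.05 in each comparison, lower to the left of 0 and higher to the right, with darker bars for changes of at least 2-fold. Counts against wild type range from 2359 in cse-2 to 13904 in med5a/b ref2.

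Over all lines, 113 of 260 list tests passed, 56 up and 57 down, and median, mean and test had the same sign in each. With an estimated correlation 8 of these passed. They were the higher detoxification list in ref3-2, cadc cadd and C4H:F5H, the lower abscisic acid, cold and drought list in ref3-3, pal1 pal2, fah1 and ref2, and the higher aliphatic glucosinolate list in ref2. Indole glucosinolate genes were called up in 9 lines and down in none of the 13, and secondary wall polysaccharides were called down in 7 lines; 5 of the former and 6 of the latter calls ended against wild-type replicates 1 to 4. Among marker lists of cell types, photosynthesis was called up in 3 lines and down in 7, epidermis and cuticle up in 1 and down in 4, cambium and cell division up in 4 and down in 1, and tracheary element death up in 2 and down in 3. Phloem markers passed in no line (smallest adjusted p = 0.259), nor did lignin polymerisation (0.0762) or sinapate esters and phenylpropanoid glycosylation (0.0639). The counts of list members below are over all genes tested. Adjusted over the list alone they were the same in 74 of the 113 called lists, and where they differ both are given.

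**Figure D2:**
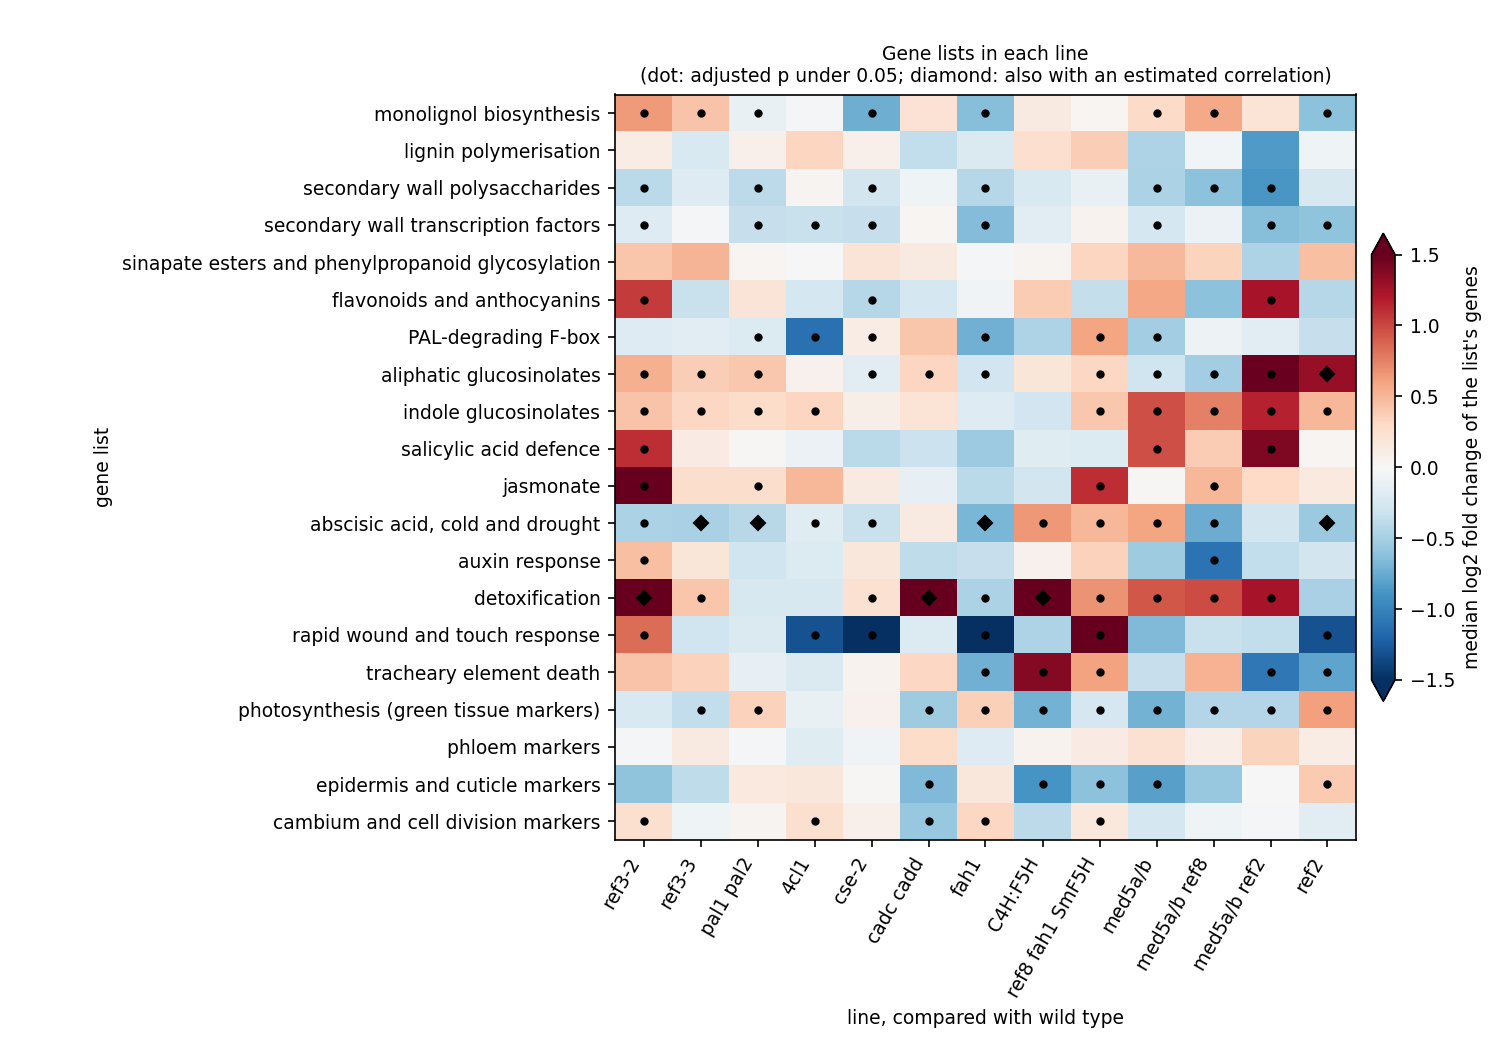
Median log2 fold change against wild type of the measured genes of each of 20 lists (vertical) in each of 13 lines (horizontal), as colour. A dot marks an adjusted p under 0.05 by camera with a preset correlation (113 of 260) and a diamond the 8 that also passed with an estimated correlation.

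Monolignol biosynthesis was called in 8 lines, up in ref3-2, ref3-3, med5a/b and med5a/b ref8 and down in pal1 pal2, cse-2, fah1 and ref2. The 7 listed genes that no line mutates (PAL4, 4CL2, HCT, CCOAOMT1, CCR1, COMT1, ATR2) give a score free of the lesions themselves. Relative to the wild-type mean it was 0.77 ± 0.07 in ref3-2, 0.73 ± 0.06 in med5a/b ref8 and 0.57 ± 0.08 in ref3-3, and −0.67 ± 0.52 in fah1, −0.52 ± 0.05 in ref2 and −0.51 ± 0.15 in cse-2 (log2, n = 4 each). In fah1, replicate 3 was at −0.02 and the others between −1.29 and −0.64. Among wild-type libraries replicate 2 was at 0.05 and replicates 1, 3 and 4 at −0.31 or below.

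**Figure D3:**
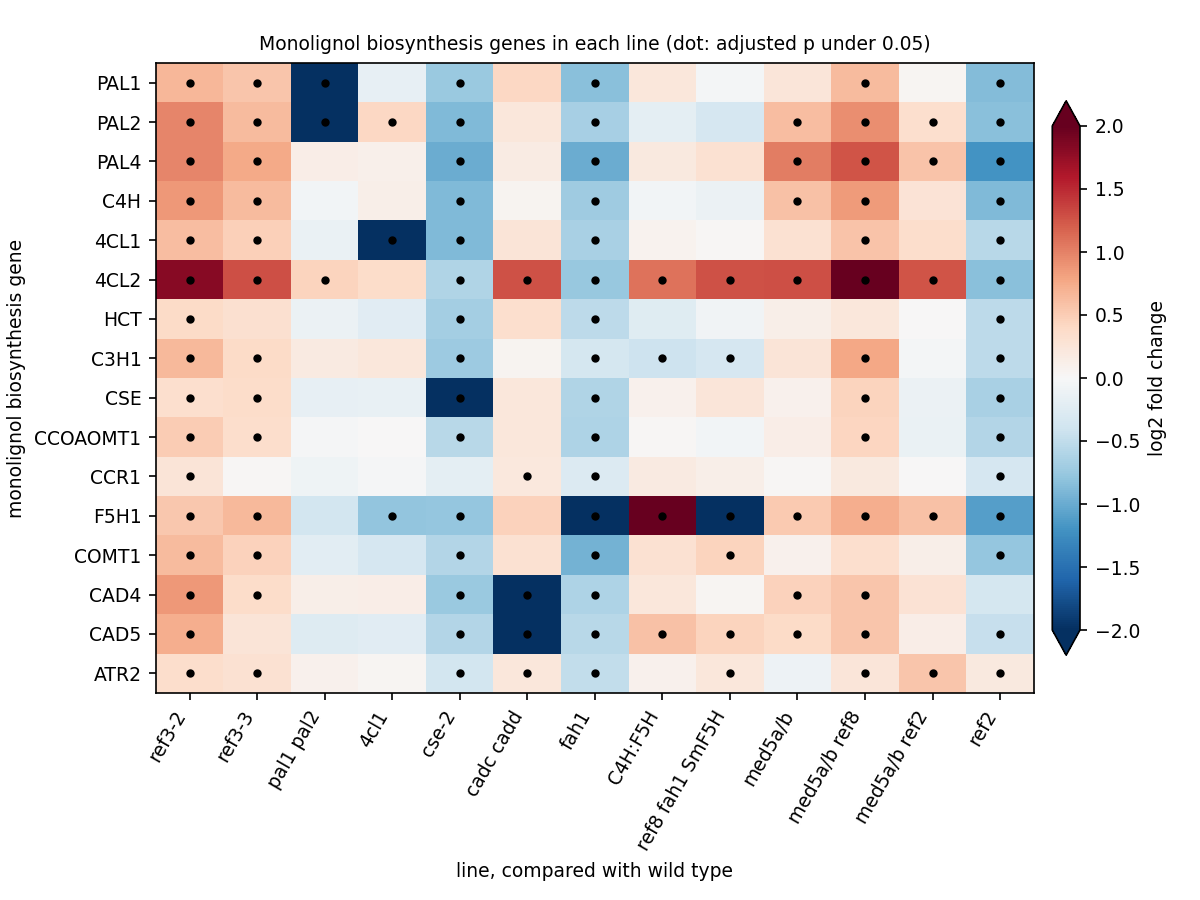
Log2 fold change against wild type of each of the 16 monolignol biosynthesis genes (vertical) in each of 13 lines (horizontal), as colour, with a dot where the adjusted p is under 0.05. All 16 genes are higher in ref3-2 and all 16 lower in fah1.

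**Figure D4:**
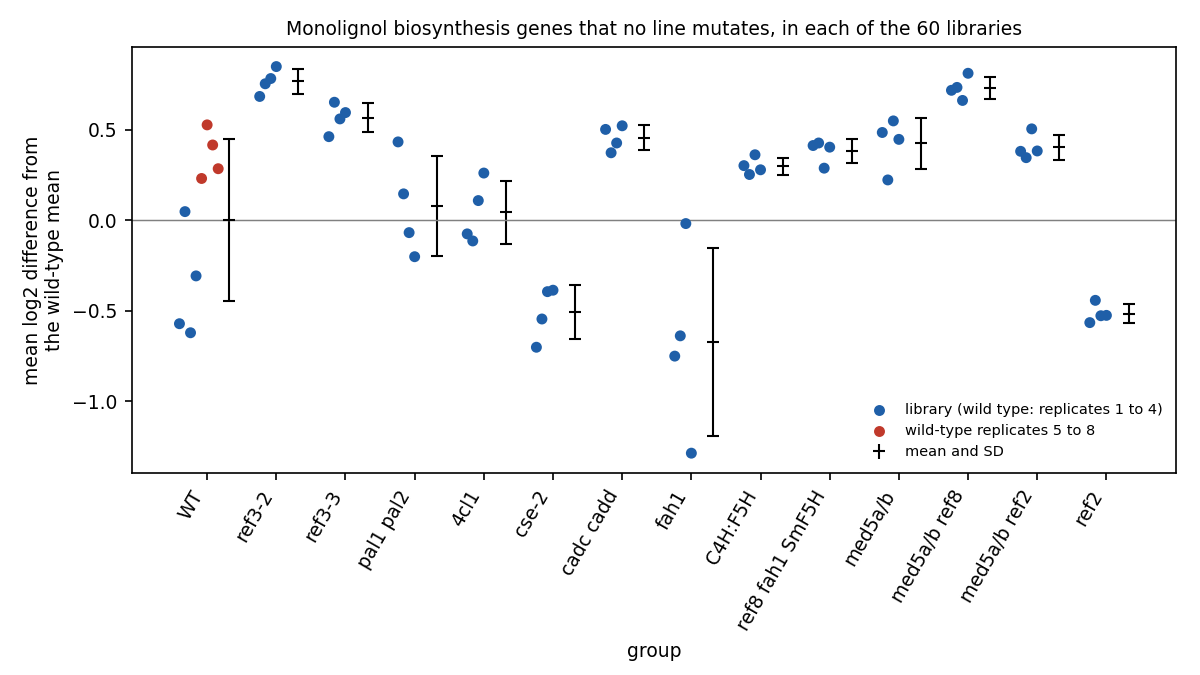
Mean log2 difference from the wild-type mean of the 7 monolignol genes that no line mutates, one point per library, with mean and SD beside them (8 wild-type libraries, replicates 5 to 8 in red, and 4 per line). Wild-type libraries run from −0.62 to 0.53, the 4 ref3-2 libraries from 0.68 to 0.85, and the 4 ref2 libraries from −0.57 to −0.44.

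The ref3 alleles weaken C4H, which hydroxylates cinnamate early in the phenylpropanoid pathway. In ref3-2 the genes of the pathway itself rose, together with genes of detoxification and defence, and 11709 genes changed, 5652 higher and 6057 lower, 1067 and 940 of them by at least 2-fold. All 16 monolignol genes were higher (16 higher, median log2 0.64, adjusted p = 0.000147, adjusted p = 0.645 with an estimated correlation). C4H rose 1.82-fold (2890 ± 117 against 1590 ± 480 CPM) and 4CL2 (AT3G21240) stood at 230 ± 10.8 CPM against 65.2 ± 24.5. Detoxification genes rose (13 higher, 2 not passing, median log2 1.98, adjusted p = 1.53e-15, adjusted p = 0.00763 with an estimated correlation). Among them CYP81D11 (AT3G28740), a cytochrome P450 induced by xenobiotics, went from 0.0162 ± 0.0254 to 36 ± 14.5 CPM (log2 10.96, and 11.82 without wild-type replicate 4), and the glutathione transferases GSTU4 (AT2G29460) and GSTU1 (AT2G29490) rose 21.8-fold and 5.21-fold. Genes of jasmonate (20 higher, 2 not passing, median log2 1.67, adjusted p = 3.84e-09) and salicylic acid defence (15 higher, 5 not passing, median log2 1.1, adjusted p = 0.000136) were also higher (adjusted p = 0.447 and 0.486 with an estimated correlation). The vegetative storage protein VSP2 (AT5G24770) rose 29-fold (1160 ± 482 against 39.9 ± 27.1 CPM), the arginase ARGAH2 (AT4G08870) 33.3-fold (107 ± 45.1 against 3.24 ± 2.1 CPM) and the glucanase PR2 (AT3G57260) 21-fold (311 ± 87.7 against 14.9 ± 6.16 CPM). Outside the lists, the glycine-rich protein GRP3S (AT2G05380) rose (129 ± 31.9 against 2.85 ± 0.696 CPM, log2 5.5 ± 0.33, adjusted p = 3.06e-19). Genes of aliphatic glucosinolates (14 higher, 1 lower, 6 not passing, median log2 0.53, adjusted p = 0.000707) and flavonoids and anthocyanins (14 higher, 1 lower, 7 not passing, median log2 1.05, adjusted p = 0.0143) were higher (adjusted p = 0.694 and 0.624 with an estimated correlation).

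In the same line, genes of abscisic acid, cold and drought (2 higher, 13 lower, 6 not passing, median log2 −0.48, adjusted p = 0.000158) fell (adjusted p = 0.341 with an estimated correlation). Lower calls were also made for secondary wall polysaccharides (11 lower, 9 not passing, median log2 −0.41, adjusted p = 0.0435) and secondary wall transcription factors (1 higher, 10 lower, 15 not passing, median log2 −0.2, adjusted p = 0.0329) (adjusted p = 0.805 and 0.786 with an estimated correlation). Among single genes, MRD1 (AT1G53480), known to respond to methionine overaccumulation, fell 104-fold (0.299 ± 0.0676 against 31.4 ± 1.7 CPM), the histidine phosphotransfer protein AHP4 (AT3G16360) 15.6-fold (0.708 ± 0.185 against 10.9 ± 2.75 CPM) and the shade-responsive PIL1 (AT2G46970) 13.7-fold (0.945 ± 0.208 against 12.9 ± 4.49 CPM). Markers of cambium and cell division (7 higher, 7 not passing, median log2 0.24, adjusted p = 0.00603) were higher (adjusted p = 0.612 with an estimated correlation). Against wild-type replicates 1 to 4 alone, the wall polysaccharide (median −0.16, adjusted p = 0.515) and wall transcription factor (0.18, adjusted p = 0.669) calls ended. The flavonoid call (0.72, adjusted p = 0.066) ended against replicates 5 to 8 alone.

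In ref3-3, the other C4H allele, cold and drought genes fell and aliphatic glucosinolate genes rose. The test called 9972 genes, 4978 higher and 4994 lower, 508 and 790 of them by at least 2-fold. Genes of abscisic acid, cold and drought (12 lower, 9 not passing, median log2 −0.48, adjusted p = 8.42e-10) fell (adjusted p = 0.0207 with an estimated correlation). The cold-induced COR15A (AT2G42540) was at 12.5 ± 3.07 CPM against 76.3 ± 13.8, and COR15B (AT2G42530) at 8.26 ± 1.8 against 37.8 ± 7.78. For aliphatic glucosinolates (16 higher, 5 not passing, 17 higher adjusted over the list alone, median log2 0.37, adjusted p = 2.24e-05) the call was upward (adjusted p = 0.612 with an estimated correlation). CYP79F2 (AT1G16400), an enzyme that converts chain-elongated methionine to aldoximes, was at 12.2 ± 1.75 CPM against 4.51 ± 0.818. Monolignol genes were higher (13 higher, 3 not passing, median log2 0.43, adjusted p = 0.000971, adjusted p = 0.694 with an estimated correlation). C4H rose 1.56-fold (log2 0.64 ± 0.16) and 4CL2 2.44-fold (159 ± 10.7 against 65.2 ± 24.5 CPM). Photosynthesis genes fell (15 lower, 7 not passing, median log2 −0.38, adjusted p = 0.000671, adjusted p = 0.706 with an estimated correlation). Outside the lists, the receptor-like kinases CRK4 (AT3G45860) (5.38 ± 1.14 against 0.616 ± 0.553 CPM, log2 3.15 ± 0.35, adjusted p = 7.66e-10) and CRK7 (AT4G23150) (5.29-fold) and the defence genes ACD6 (AT4G14400) (5.29-fold) and LURP1 (AT2G14560) (5.49-fold) were higher. UGT72E2 (AT5G66690), a monolignol glucosyltransferase, was 6.63-fold lower and the sulfotransferase ST4B (AT1G13420) 9.05-fold lower. Against wild-type replicates 5 to 8 alone 6544 genes changed, and the monolignol (median 0.11, adjusted p = 0.206), photosynthesis (−0.18, adjusted p = 0.102) and C4H (log2 0.29, adjusted p = 0.128) calls ended.

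The alleles ref3-2 and ref3-3 differed in 8389 genes, 4004 higher and 4385 lower, 680 and 330 by at least 2-fold. ARGAH2 was 28.3-fold higher in ref3-2 (107 ± 45.1 against 3.79 ± 0.631 CPM), VSP1 (AT5G24780) 18.7-fold (360 ± 199 against 19.3 ± 7.64 CPM), and LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis, stood at 68.6 ± 29.5 against 2.61 ± 3.64 CPM (log2 4.74, and 6.45 without ref3-3 replicate 1). MRD1 was lower (0.299 ± 0.0676 against 34.3 ± 2.83 CPM, log2 −6.83 ± 0.37, adjusted p = 3.88e-20), as were PIL1 (0.945 ± 0.208 against 10.7 ± 4.15 CPM) and AHP4 (0.708 ± 0.185 against 7.51 ± 1.58 CPM). Against wild type, 2764 genes rose and 3125 fell in both alleles and 556 went opposite ways, where independent lists of these sizes would share 1326 and 1426. Over all genes the 2 sets of fold changes had a covariance of 0.334 (r = 0.67), against 0.019 (r = 0.35) and no shared call for simulated unchanged groups with the same controls. With wild type divided between the alleles, 4421 or 4140 calls were shared in one direction, and 192 or 2187 went opposite ways (r = 0.6 or 0.3).

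PAL makes cinnamate from phenylalanine and supplies the whole pathway, and pal1 pal2 tests a reduced entry. In this line cold and drought genes fell while aliphatic glucosinolate and photosynthesis genes rose. The test called 5083 genes, 2396 higher and 2687 lower, 190 and 173 of them by at least 2-fold. Genes of abscisic acid, cold and drought (14 lower, 7 not passing, 15 lower adjusted over the list alone, median log2 −0.42, adjusted p = 3.11e-12) fell (adjusted p = 0.00763 with an estimated correlation). Among them RD29A (AT5G52310) was 3.31-fold lower (261 ± 60.9 against 863 ± 109 CPM) and the dehydrin LTI30 (AT3G50970) 2.73-fold. Genes of aliphatic glucosinolates (15 higher, 6 not passing, 17 higher and 1 lower adjusted over the list alone, median log2 0.4, adjusted p = 2.7e-08) and photosynthesis (11 higher, 11 not passing, 16 higher adjusted over the list alone, median log2 0.35, adjusted p = 7.37e-07) rose (adjusted p = 0.511 and 0.592 with an estimated correlation). CYP79F2 rose 2.21-fold, the regulator MYB76 (AT5G07700) 1.61-fold and the Rubisco small subunit RBCS1B (AT5G38430) 2.08-fold (117 ± 45.3 against 56.3 ± 20.6 CPM). Calls were downward for secondary wall transcription factors (10 lower, 16 not passing, 12 lower adjusted over the list alone, median log2 −0.34, adjusted p = 8.77e-06) and secondary wall polysaccharides (8 lower, 12 not passing, 10 lower adjusted over the list alone, median log2 −0.39, adjusted p = 0.000233) (adjusted p = 0.565 and 0.645 with an estimated correlation). MYB54 (AT1G73410) was 1.84-fold and MYB7 (AT2G16720) 1.57-fold lower. The monolignol list was called down (1 higher, 2 lower, 13 not passing, 2 lower adjusted over the list alone, median log2 −0.11, adjusted p = 0.0129, adjusted p = 0.772 with an estimated correlation). Without PAL1 and PAL2 its median was −0.07 and its test pointed up (adjusted p = 0.914). The kinase WNK9 (AT5G28080) rose 6.3-fold (5.68 ± 0.591 against 0.903 ± 0.211 CPM) and VSP1 6.65-fold (log2 2.73, and 1.96 without pal1 pal2 replicate 4). QQS (AT3G30720), an orphan gene linked to starch and protein allocation, fell 4.17-fold (5.46 ± 3.19 against 22.6 ± 8.02 CPM).

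In pal1 pal2, replicate 1 stood apart, with a chi-square per gene of 50.68 to 116.3 to the others and a score over the 7 unmutated monolignol genes of 0.43 against −0.2 to 0.15. Leaving out replicate 4 left 3160 changed genes, the fit of only pal1 pal2 and wild type gave 2102, and wild-type replicates 5 to 8 alone gave 8337. Against replicates 1 to 4 alone the monolignol (median 0.31, adjusted p = 0.326), wall polysaccharide (−0.13, adjusted p = 0.2) and wall transcription factor (−0.06, adjusted p = 0.149) calls ended.

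4CL1 activates hydroxycinnamates to their CoA esters. In 4cl1 the F-box genes that act on PAL and the wound and touch genes fell, and markers of the cambium rose. The test called 6687 genes, 3401 higher and 3286 lower, 92 and 400 of them by at least 2-fold. All 4 Kelch-repeat F-box genes whose products target PAL for degradation fell (4 lower, median log2 −1.12, adjusted p = 0.000233, adjusted p = 0.218 with an estimated correlation), KFB20 (AT1G80440) 3.71-fold and KFB39 (AT2G44130) 2.64-fold, to 13.1 ± 2.8 CPM from 34.6 ± 4.33. Genes of rapid wound and touch responses (12 lower, 4 not passing, median log2 −1.31, adjusted p = 0.000237) were lower (adjusted p = 0.612 with an estimated correlation). The zinc-finger gene ZAT12 (AT5G59820) fell 5.5-fold (1.81 ± 0.143 against 9.97 ± 8.65 CPM) and the ethylene-responsive factor ERF11 (AT1G28370) 5.13-fold. Secondary wall transcription factors were called down (3 higher, 10 lower, 13 not passing, 3 higher and 13 lower adjusted over the list alone, median log2 −0.34, adjusted p = 0.003, adjusted p = 0.697 with an estimated correlation). Markers of cambium and cell division (6 higher, 8 not passing, 7 higher adjusted over the list alone, median log2 0.24, adjusted p = 0.007) rose (adjusted p = 0.612 with an estimated correlation). PXY (AT5G61480), a receptor kinase of the vascular cambium, was at 307 ± 9.31 CPM against 246 ± 24.9. COR27 (AT5G42900), a cold- and light-regulated gene, rose 2.34-fold (7.71 ± 0.83 against 3.3 ± 0.869 CPM), the defence-related cinnamoyl-CoA reductase CCR2 (AT1G80820) 2.28-fold (3 ± 0.916 against 1.32 ± 0.442 CPM) and JMJD5 (AT3G20810) 2.15-fold. MRD1 fell 28.5-fold to 1.11 ± 0.982 CPM (log2 −4.83, and −5.66 without 4cl1 replicate 4), the sulphur-starvation gene LSU3 (AT3G49570) 7.74-fold and the senescence regulator NAP (AT1G69490) 5.43-fold. Against wild-type replicates 1 to 4 alone 3723 genes passed, with just 4cl1 and wild type fitted 3887. The wall transcription factor call (median 0.01, adjusted p = 0.6) ended against replicates 1 to 4 and the wound call (−0.68, adjusted p = 0.271) against 5 to 8.

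CSE releases caffeate from caffeoyl shikimate. The cse-2 line had the fewest changed genes against all 8 wild-type libraries, and genes of the monolignol pathway and of wound and touch responses were lower in it. In all, 2359 genes changed, 767 higher and 1592 lower, 76 and 250 of them by at least 2-fold. Monolignol genes fell (15 lower, 1 not passing, 16 lower adjusted over the list alone, median log2 −0.73, adjusted p = 1.19e-20, adjusted p = 0.189 with an estimated correlation). The named members besides CSE were PAL4 (AT3G10340), at 299 ± 50.4 CPM against 599 ± 258, and 4CL1, at 735 ± 74.4 against 1360 ± 519. Genes of rapid wound and touch responses (13 lower, 3 not passing, 16 lower adjusted over the list alone, median log2 −1.77, adjusted p = 4.99e-11) and abscisic acid, cold and drought (1 higher, 8 lower, 12 not passing, 1 higher and 10 lower adjusted over the list alone, median log2 −0.33, adjusted p = 7.92e-06) were lower (adjusted p = 0.405 and 0.189 with an estimated correlation). ERF11 fell 7.82-fold (0.385 ± 0.176 against 3 ± 1.74 CPM), ZAT12 6.35-fold (1.58 ± 0.417 against 9.97 ± 8.65 CPM), COR15B 1.97-fold and RD29A 1.7-fold. Genes of flavonoids and anthocyanins (7 lower, 15 not passing, 11 lower adjusted over the list alone, median log2 −0.42, adjusted p = 0.000673) fell (adjusted p = 0.506 with an estimated correlation). Calls were downward for secondary wall transcription factors (2 higher, 6 lower, 18 not passing, median log2 −0.34, adjusted p = 0.000372) and secondary wall polysaccharides (20 not passing, median log2 −0.28, adjusted p = 0.00603) (adjusted p = 0.645 and 0.758 with an estimated correlation). The vessel regulator XND1 (AT5G64530) was 2.3-fold lower (5.39 ± 1.15 against 12.4 ± 1.88 CPM) and the lignin regulator MYB58 (AT1G16490) 1.96-fold (12.2 ± 1.36 against 23.9 ± 4.4 CPM). The iron store ferritin FER1 (AT5G01600) (811 ± 136 against 282 ± 20.6 CPM, log2 1.53 ± 0.09, adjusted p = 1.12e-18) and the glucosyltransferase UGT73B1 (AT4G34138) (2.89-fold, 32.6 ± 6.37 against 11.3 ± 2.88 CPM) rose. MRD1 fell 103-fold (0.308 ± 0.0897 against 31.4 ± 1.7 CPM) and ARGAH2 14.1-fold (0.23 ± 0.0704 against 3.24 ± 2.1 CPM).

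The count was 1476 without cse-2 replicate 1, 1384 without replicate 2, 1093 with just cse-2 and wild type fitted, 1423 against wild-type replicates 1 to 4 alone and 7411 against 5 to 8 alone, where ref3-3 (6544) and cadc cadd (7210) had fewer. Against replicates 1 to 4, the monolignol median was −0.22, and the calls ended for wall polysaccharides (median −0.001, adjusted p = 0.92), wall transcription factors (0.07, adjusted p = 0.733), PAL4 (log2 −0.33, adjusted p = 0.423) and 4CL1 (log2 −0.33, adjusted p = 0.355).

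CAD4 and CAD5 reduce cinnamaldehydes to the alcohols from which lignin is made. In cadc cadd detoxification genes rose and photosynthesis, epidermis and cambium genes fell. The test called 10658 genes, 5039 higher and 5619 lower, 515 and 886 of them by at least 2-fold. Detoxification genes were higher (12 higher, 3 not passing, median log2 2.83, adjusted p = 1.42e-41, adjusted p = 1.28e-05 with an estimated correlation). CYP81D11 rose from 0.0162 ± 0.0254 to 36.4 ± 9.52 CPM, GSTU1 from 1.77 ± 0.139 to 37 ± 11.8 and the glutathione transferase GSTU25 (AT1G17180) from 0.1 ± 0.0462 to 9.93 ± 11.1. The glucosyltransferase UGT73B3 (AT4G34131) (16.8 ± 6.34 against 0.59 ± 0.182 CPM, log2 4.82 ± 0.22, adjusted p = 9.83e-24), UGT73B1 (12.2-fold) and the transcription factor WRKY45 (AT3G01970) (13.6-fold) were higher. All 22 photosynthesis genes fell (22 lower, median log2 −0.53, adjusted p = 8.71e-09, adjusted p = 0.546 with an estimated correlation), the antenna genes LHCB1.1 (AT1G29920) 2.54-fold (391 ± 54.9 against 992 ± 239 CPM) and LHCB1.2 (AT1G29910) 2.27-fold. Markers of the epidermis and cuticle (8 lower, 1 not passing, median log2 −0.66, adjusted p = 0.00485) and cambium and cell division (3 higher, 9 lower, 2 not passing, median log2 −0.57, adjusted p = 0.00603) were lower (adjusted p = 0.52 and 0.612 with an estimated correlation). The wax gene CER1 (AT1G02205) fell 2.28-fold (225 ± 47.9 against 513 ± 204 CPM). The fatty acid elongation gene KCS19 (AT5G04530) fell 21.1-fold (0.242 ± 0.279 against 5.24 ± 3.1 CPM) and the gibberellin oxidase ATGA2OX1 (AT1G78440) 12-fold (0.917 ± 0.187 against 11.1 ± 7.07 CPM). Leaving out 1 library moved GSTU25 from log2 6.59 to 5.47 (cadc cadd replicate 4), KCS19 from −4.4 to −5.4 (cadc cadd replicate 2) and CYP81D11 from 10.97 to 11.83 (wild-type replicate 4). Each of these list calls passed against either set of wild-type replicates.

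F5H1 directs the pathway towards syringyl units, which fah1 lacks. In fah1 all 16 monolignol genes fell, with secondary wall, wound, cold and drought genes, while photosynthesis and cambium genes rose. In total 11140 genes changed, 5256 higher and 5884 lower, 321 and 866 of them by at least 2-fold. The monolignol genes (16 lower, median log2 −0.63, adjusted p = 3.61e-06, adjusted p = 0.565 with an estimated correlation) included COMT1 (AT5G54160), the methyltransferase that follows F5H1, 1.92-fold lower (999 ± 401 against 1920 ± 650 CPM). Genes for secondary wall transcription factors (21 lower, 5 not passing, 22 lower adjusted over the list alone, median log2 −0.65, adjusted p = 8.22e-06) and secondary wall polysaccharides (12 lower, 8 not passing, 13 lower adjusted over the list alone, median log2 −0.42, adjusted p = 0.00603) fell (adjusted p = 0.565 and 0.758 with an estimated correlation). Genes of tracheary element death (4 lower, 2 not passing, 6 lower adjusted over the list alone, median log2 −0.72, adjusted p = 0.0107) were also lower (adjusted p = 0.565 with an estimated correlation). Lower calls were made for abscisic acid, cold and drought (18 lower, 3 not passing, 1 higher and 18 lower adjusted over the list alone, median log2 −0.69, adjusted p = 4.42e-12) and rapid wound and touch responses (15 lower, 1 not passing, 16 lower adjusted over the list alone, median log2 −2.19, adjusted p = 6.35e-06) (adjusted p = 0.00763 and 0.546 with an estimated correlation). Among them RD29A fell 3.65-fold (236 ± 22.9 against 863 ± 109 CPM), NCED3 (AT3G14440), which makes the precursor of abscisic acid, 6.06-fold and ERF11 16.4-fold (0.183 ± 0.0673 against 3 ± 1.74 CPM). The cold regulator CBF1 (AT4G25490), outside the wound list, fell 15.1-fold (log2 −3.91, and −3.14 without wild-type replicate 1). Markers of photosynthesis (16 higher, 6 not passing, median log2 0.36, adjusted p = 0.00025) and cambium and cell division (9 higher, 2 lower, 3 not passing, median log2 0.31, adjusted p = 0.0206) were higher (adjusted p = 0.694 and 0.645 with an estimated correlation). All 4 PAL-degrading F-box genes were lower (4 lower, median log2 −0.72, adjusted p = 0.017, adjusted p = 0.506 with an estimated correlation). VSP1 rose 4.27-fold (68.1 ± 21.9 against 16 ± 11.4 CPM), the ADP/ATP carrier AAC2 (AT5G13490) 2.78-fold and UGT72E2 2.47-fold. Replicate 3 stood apart, with a chi-square per gene of 63.05 to 183.9 to the others. Against wild-type replicates 1 to 4 alone 7117 genes passed, the wall polysaccharide (median −0.12, adjusted p = 0.179) and tracheary element (−0.42, adjusted p = 0.102) calls ended, and the monolignol median was −0.25.

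C4H:F5H carries F5H1 behind the C4H promoter and makes lignin rich in syringyl units. Detoxification, drought and cell death genes rose in it and photosynthesis and epidermis genes fell. The test called 12591 genes, 5996 higher and 6595 lower, 920 and 1763 of them by at least 2-fold. F5H1 rose 61.5-fold (25600 ± 1090 against 416 ± 217 CPM). Detoxification genes were higher (13 higher, 2 not passing, median log2 2.7, adjusted p = 3.74e-25, adjusted p = 0.000578 with an estimated correlation), with CYP81D11 at 96.8 ± 8.26 CPM against 0.0162 ± 0.0254 and GSTU25 at 51.2 ± 2.9 against 0.1 ± 0.0462. Outside the list, UGT73B3 rose 58.4-fold (34.7 ± 2.79 against 0.59 ± 0.182 CPM) and the dehydrogenase G6PD4 (AT1G09420) 15.6-fold (96.6 ± 3.3 against 6.18 ± 1.36 CPM). Genes of abscisic acid, cold and drought (14 higher, 2 lower, 5 not passing, 15 higher and 2 lower adjusted over the list alone, median log2 0.65, adjusted p = 0.000624) and tracheary element death (6 higher, median log2 1.38, adjusted p = 0.000703) rose (adjusted p = 0.448 and 0.486 with an estimated correlation). Examples were LTI30 (3.12-fold, 598 ± 47.3 against 192 ± 22.8 CPM), NCED3 (3.84-fold), the metacaspase MC9 (AT5G04200) (3.36-fold, 314 ± 4.36 against 93.5 ± 35.9 CPM) and the nuclease BFN1 (AT1G11190) (3.03-fold, 63.7 ± 1.86 against 21 ± 6.23 CPM). Genes of photosynthesis (20 lower, 2 not passing, median log2 −0.71, adjusted p = 6.64e-08) and the epidermis and cuticle (8 lower, 1 not passing, median log2 −0.88, adjusted p = 0.00322) fell (adjusted p = 0.565 and 0.506 with an estimated correlation). The antenna gene LHCB2.1 (AT2G05100) fell to 179 ± 40.6 CPM from 1160 ± 129. The floral inducer FT (AT1G65480) rose (14.2 ± 1.18 against 0.536 ± 0.165 CPM, log2 4.72 ± 0.32, adjusted p = 9.83e-18). MAF4 (AT5G65070), a repressor of flowering, had no read in the line and was at least 28.1-fold lower than its wild-type level of 1.53 ± 0.407 CPM. PAI3 (AT1G29410), an enzyme of tryptophan synthesis, was at 0.0855 ± 0.082 CPM against 8.75 ± 0.462, and the terpene synthase TPS14 (AT1G61680) was 93.3-fold lower. PAI3 moved from log2 −6.75 to −7.44 without C4H:F5H replicate 2 and CYP81D11 from 12.38 to 13.25 without wild-type replicate 4. All these list calls passed with either wild-type set.

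Genes at least 8-fold lower in C4H:F5H than in wild type, and in no other line, numbered 176, and 74 were as much higher. Of the tested genes, 1.83% on chromosome 5 and 1.13% on chromosome 2 were among the 176, against 0.311 to 0.445% on the others. In bins of 100 neighbouring genes, 17 lay between AT5G44100 and AT5G45275 on chromosome 5, where 10000 random placements gave at most 9 and no other line had more than 2 in a bin. This split by position was chosen after the values were seen.

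**Figure D5:**
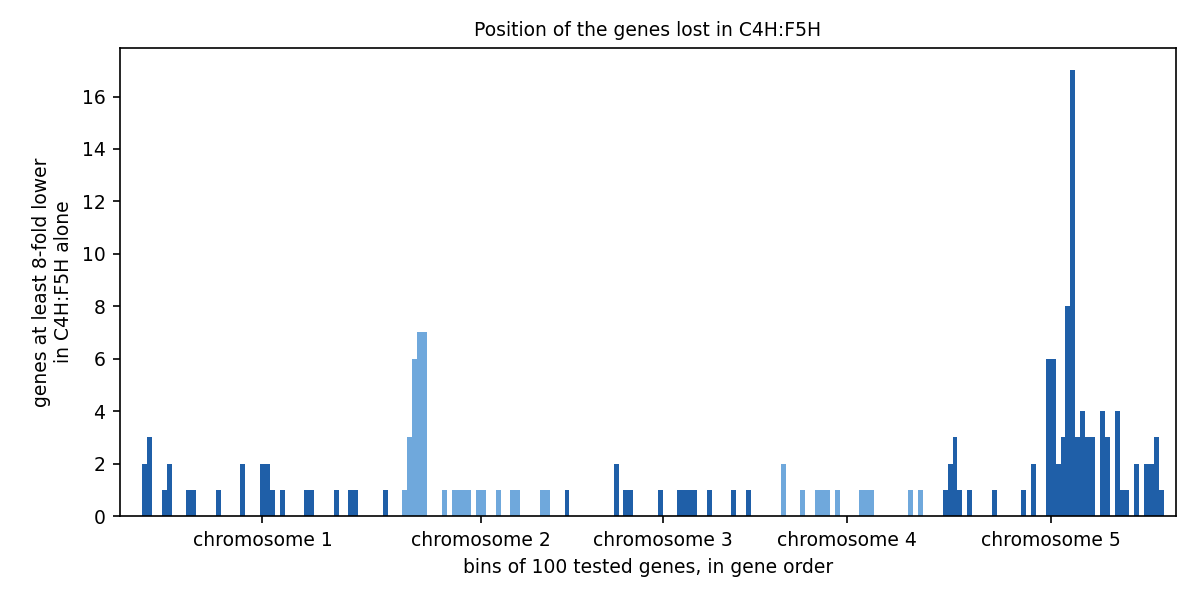
Number of genes at least 8-fold lower in C4H:F5H alone (vertical) in each bin of 100 tested genes in chromosome order (horizontal), with shades alternating by chromosome. One bin on chromosome 5 holds 17.

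C4H:F5H against fah1 compares the extremes of lignin composition, and 14551 genes changed, 7144 higher and 7407 lower, 1877 and 2241 of them by at least 2-fold. F5H1 differed 912-fold (25600 ± 1090 against 28 ± 6.98 CPM, n = 4 each). FT (14.2 ± 1.18 against 0.0758 ± 0.0249 CPM, log2 7.5 ± 0.54, adjusted p = 7.39e-17) and UGT73B3 (69.4-fold) were higher in C4H:F5H. PRP2 (AT2G21140), a proline-rich protein of the wall, was 592-fold lower (0.166 ± 0.0766 against 92.4 ± 65.4 CPM) and the germin GER3 (AT5G20630) 304-fold (0.269 ± 0.147 against 88 ± 59.6 CPM). MAF4 was at least 26.6-fold lower than its level of 1.44 ± 0.565 CPM in fah1.

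The line ref8 fah1 SmF5H carries lesions of C3H1 and F5H1 and expresses an F5H of the lycophyte Selaginella, whose transcript was not analysed here. Wound and touch, jasmonate and drought genes rose in it, and 9953 genes changed, 4629 higher and 5324 lower, 858 and 974 of them by at least 2-fold. All 16 genes of the wound and touch list were higher (16 higher, median log2 1.67, adjusted p = 3.28e-06, adjusted p = 0.511 with an estimated correlation), with WRKY33 (AT2G38470) at 87.5 ± 38.3 CPM against 16.1 ± 7.3 and ERF11 6.21-fold higher. Genes of jasmonate (15 higher, 7 not passing, 16 higher adjusted over the list alone, median log2 1.11, adjusted p = 2.35e-06) and abscisic acid, cold and drought (13 higher, 1 lower, 7 not passing, median log2 0.5, adjusted p = 1.13e-05) rose (adjusted p = 0.506 and 0.189 with an estimated correlation). The lipoxygenase LOX4 (AT1G72520) rose 6.26-fold (35.1 ± 25 against 5.6 ± 1.82 CPM), the repressor JAZ8 (AT1G30135) 13-fold (2.56 ± 1.55 against 0.194 ± 0.0612 CPM), the phosphatase HAI1 (AT5G59220) 4.13-fold and KIN1 (AT5G15960) 3.76-fold. Genes of detoxification (7 higher, 8 not passing, median log2 0.67, adjusted p = 0.000181) and aliphatic glucosinolates (13 higher, 8 not passing, 14 higher adjusted over the list alone, median log2 0.31, adjusted p = 0.000233) were higher (adjusted p = 0.469 and 0.645 with an estimated correlation). All 6 tracheary element death genes rose (6 higher, median log2 0.6, adjusted p = 0.00288, adjusted p = 0.506 with an estimated correlation). Markers of the epidermis and cuticle (7 lower, 2 not passing, median log2 −0.61, adjusted p = 0.00278) and photosynthesis (11 lower, 11 not passing, 12 lower adjusted over the list alone, median log2 −0.25, adjusted p = 0.0222) were lower (adjusted p = 0.506 and 0.791 with an estimated correlation). The myrosinase-binding protein MBP1 (AT1G52040) rose 19-fold (56.7 ± 35.4 against 2.99 ± 2.55 CPM) and CCR2 9.31-fold (12.3 ± 2.65 against 1.32 ± 0.442 CPM), and KCS19 fell 20.3-fold (0.258 ± 0.132 against 5.24 ± 3.1 CPM) and ST4B 21.6-fold (0.254 ± 0.126 against 5.53 ± 4.02 CPM). C3H1 was 1.26-fold lower (log2 −0.33 ± 0.14, adjusted p = 0.044), a call that ended with no filter on low counts (adjusted p = 0.0608), against wild-type replicates 1 to 4 alone (log2 0), and without any one of wild-type replicates 2 and 5 to 8 or the line's own 1, 3 and 4 (log2 −0.34 to −0.25, adjusted p = 0.0578 to 0.202). The tracheary element (median 0.32, adjusted p = 0.0595) and photosynthesis (−0.09, adjusted p = 0.573) calls ended against wild-type replicates 5 to 8 alone.

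MED5A and MED5B are subunits of Mediator, which links transcription factors to RNA polymerase. Their loss restores growth of some lignin mutants. In med5a/b defence, indole glucosinolate and detoxification genes rose and photosynthesis genes fell. The test called 12142 genes, 5844 higher and 6298 lower, 973 and 1113 by at least 2-fold. Genes of salicylic acid defence (16 higher, 4 not passing, median log2 0.97, adjusted p = 0.000178) and indole glucosinolates (9 higher, 4 lower, 1 not passing, 10 higher and 4 lower adjusted over the list alone, median log2 0.97, adjusted p = 0.00251) rose (adjusted p = 0.486 and 0.506 with an estimated correlation). WRKY38 (AT5G22570) was 18.7-fold and CYP81F2 (AT5G57220), an indole glucosinolate hydroxylase, 5.24-fold higher, and PR1 (AT2G14610) stood at 2.89 ± 2.46 CPM against 0.0404 ± 0.0808 (log2 6.13, and 7.59 without wild-type replicate 3). The basic chitinase HCHIB (AT3G12500) (172 ± 218 against 0.605 ± 0.267 CPM), the extensin EXT4 (AT1G76930) (306 ± 379 against 1.28 ± 0.799 CPM) and PR4 (AT3G04720) (1250 ± 1050 against 43.4 ± 25.4 CPM) rose 280-fold, 244-fold and 28.8-fold, and their log2 changes of 8.13, 7.93 and 4.85 were 6.79, 6.71 and 4.22 without med5a/b replicate 1. Genes of detoxification (8 higher, 7 not passing, median log2 0.94, adjusted p = 0.000995) and abscisic acid, cold and drought (12 higher, 2 lower, 7 not passing, median log2 0.59, adjusted p = 0.00412) were higher (adjusted p = 0.506 and 0.506 with an estimated correlation). The glutathione transferase GSTF6 (AT1G02930) rose 18-fold. Photosynthesis genes fell (21 lower, 1 not passing, median log2 −0.71, adjusted p = 6.95e-10, adjusted p = 0.506 with an estimated correlation), LHCB1.1 2.16-fold (460 ± 220 against 992 ± 239 CPM). Replicate 2 had a chi-square per gene of 64.97 to 135.1 to the others, which had 23.67 to 78.43 among themselves. It also had RBCS3B at 559 against 178 to 221 CPM and a photosynthesis (green tissue markers) score of −0.002 against −0.972 to −0.65. Lower calls were made for secondary wall polysaccharides (14 lower, 6 not passing, median log2 −0.48, adjusted p = 0.00515) and secondary wall transcription factors (2 higher, 10 lower, 14 not passing, median log2 −0.27, adjusted p = 0.0144) (adjusted p = 0.758 and 0.758 with an estimated correlation). The monolignol list was called up (7 higher, 9 not passing, 5 higher adjusted over the list alone, median log2 0.29, adjusted p = 0.0443, adjusted p = 0.791 with an estimated correlation). Markers of the epidermis and cuticle (6 lower, 3 not passing, 7 lower adjusted over the list alone, median log2 −0.82, adjusted p = 0.0227) were lower (adjusted p = 0.612 with an estimated correlation). The xyloglucan endotransglucosylase XTH18 (AT4G30280) fell 31.5-fold (0.366 ± 0.466 against 11.1 ± 14.9 CPM) and the inositol oxygenase MIOX4 (AT4G26260) 7.64-fold (3.59 ± 0.579 against 27.5 ± 11.1 CPM). The XTH18 change of log2 −4.98 was −4.16 without wild-type replicate 1 and −6.23 without med5a/b replicate 2. Calls for wall polysaccharides (median −0.18, adjusted p = 0.234) and wall transcription factors (0.13, adjusted p = 0.587) ended against wild-type replicates 1 to 4 alone, and those for monolignol genes (−0.04, adjusted p = 0.85) and the epidermis (−0.2, adjusted p = 0.142) against 5 to 8 alone. The monolignol call also ended without wild-type replicate 1 (adjusted p = 0.106) or 3 (adjusted p = 0.108).

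The line med5a/b ref8 adds the C3H1 lesion to the Mediator mutations. Monolignol and detoxification genes rose in it, and cold, aliphatic glucosinolate, wall polysaccharide and photosynthesis genes fell. The test called 11841 genes, 5920 higher and 5921 lower, 937 and 1219 of them by at least 2-fold. Replicate 2 stood apart (chi-square per gene 53.91 to 125.2 to the others, 28.19 to 42.13 among them). Monolignol genes were higher (13 higher, 3 not passing, 14 higher adjusted over the list alone, median log2 0.56, adjusted p = 0.000233, adjusted p = 0.645 with an estimated correlation), 4CL2 3.97-fold and PAL4 2.38-fold (1430 ± 71.1 against 599 ± 258 CPM). HCHIB (305 ± 194 against 0.605 ± 0.267 CPM), EXT4 (486 ± 342 against 1.28 ± 0.799), PR4 (57.3-fold) and the nitrate transporter NRT1.8 (AT4G21680) (104 ± 71.1 against 0.492 ± 0.305) rose. Detoxification genes rose (10 higher, 5 not passing, 11 higher adjusted over the list alone, median log2 0.98, adjusted p = 8.11e-07, adjusted p = 0.199 with an estimated correlation), GSTU4 24.6-fold. Genes of abscisic acid, cold and drought (2 higher, 10 lower, 9 not passing, median log2 −0.75, adjusted p = 8.28e-06) and aliphatic glucosinolates (1 higher, 19 lower, 1 not passing, median log2 −0.53, adjusted p = 2.07e-05) fell (adjusted p = 0.189 and 0.612 with an estimated correlation). COR15A fell 5.56-fold (13.8 ± 3.13 against 76.3 ± 13.8 CPM) and COR6.6 (AT5G15970) 4.39-fold. Genes for secondary wall polysaccharides (16 lower, 4 not passing, 17 lower adjusted over the list alone, median log2 −0.62, adjusted p = 0.000374) and photosynthesis (17 lower, 5 not passing, 19 lower adjusted over the list alone, median log2 −0.44, adjusted p = 0.000471) were lower (adjusted p = 0.67 and 0.702 with an estimated correlation). XTH18 fell 39.2-fold (0.281 ± 0.14 against 11.1 ± 14.9 CPM; log2 −5.29, and −4.49 without wild-type replicate 1) and KCS19 13.3-fold (0.398 ± 0.178 against 5.24 ± 3.1 CPM). The wall polysaccharide call (median −0.41, adjusted p = 0.0801) ended against wild-type replicates 1 to 4 alone.

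Against med5a/b, med5a/b ref8 had 4736 changed genes, 2412 higher and 2324 lower, 300 and 416 by at least 2-fold. QQS (74.5 ± 5.83 against 5.81 ± 1.29 CPM, log2 3.68 ± 0.34, adjusted p = 2.83e-12), MRD1 (41.1 ± 1.42 against 4.25 ± 1.92 CPM, log2 3.29 ± 0.27, adjusted p = 1.19e-13) and HEI10 (AT1G53490), a gene of meiotic crossovers (7.77-fold, 15.5 ± 9.4 against 2 ± 0.732 CPM), were higher in med5a/b ref8. The receptor-like protein RLP33 (AT3G05660) (0.731 ± 0.194 against 12.2 ± 1.45 CPM, log2 −4.07 ± 0.25, adjusted p = 4.62e-18) and COR15B (9.25-fold) were lower. A fit of these 8 libraries alone called 2737 genes. Relative to wild type, med5a/b and med5a/b ref8 shared 4048 higher and 4287 lower genes with 333 opposite, where independent lists would share 1631 and 1757. The covariance of their fold changes was 0.665 (r = 0.82) against a simulated 0.0187 (r = 0.34), and with wild type divided between them 6235 or 6069 calls were shared and 514 or 852 opposite (r = 0.68 or 0.65).

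CYP83A1, mutated in ref2, oxidises the aldoximes of aliphatic glucosinolate synthesis, and its loss also lowers phenylpropanoids. In ref2 glucosinolate and photosynthesis genes rose, and drought, wound, monolignol and wall regulator genes fell. The test called 8363 genes, 3926 higher and 4437 lower, 321 and 627 by at least 2-fold. Genes of aliphatic glucosinolates (19 higher, 1 lower, 1 not passing, median log2 1.31, adjusted p = 9.2e-37) and indole glucosinolates (7 higher, 1 lower, 6 not passing, median log2 0.5, adjusted p = 3.05e-06) rose (adjusted p = 0.0247 and 0.189 with an estimated correlation), CYP83A1 being the lower aliphatic member. CYP79F2, which acts just before CYP83A1, was at 23.8 ± 3.51 CPM against 4.51 ± 0.818, and MYB76 at 42.3 ± 5.57 against 14.3 ± 2.13. Of the indole list, SUR1 (AT2G20610) rose 2.07-fold (792 ± 29.7 against 384 ± 32.2 CPM) and UGT74B1 (AT1G24100) 2.12-fold (372 ± 12.8 against 175 ± 14.7 CPM). Whether both also serve the aliphatic branch was not tested. The regulator MYB51 (AT1G18570) fell 2.12-fold (5.31 ± 0.717 against 11.2 ± 2.49 CPM). Photosynthesis genes rose (21 higher, 1 not passing, median log2 0.61, adjusted p = 6.25e-13, adjusted p = 0.486 with an estimated correlation), RBCS1B 2.89-fold and RBCS3B (AT5G38410) 2.68-fold. Genes of abscisic acid, cold and drought (15 lower, 6 not passing, 16 lower adjusted over the list alone, median log2 −0.55, adjusted p = 4.11e-12) fell (adjusted p = 0.00763 with an estimated correlation). LTI30 fell 3.25-fold (59.1 ± 4 against 192 ± 22.8 CPM) and KIN1 4.8-fold. Lower calls were made for monolignol biosynthesis (1 higher, 14 lower, 1 not passing, 1 higher and 15 lower adjusted over the list alone, median log2 −0.61, adjusted p = 0.00026) and secondary wall transcription factors (1 higher, 17 lower, 8 not passing, 1 higher and 19 lower adjusted over the list alone, median log2 −0.6, adjusted p = 0.000617) (adjusted p = 0.645 and 0.645 with an estimated correlation). Genes of tracheary element death (5 lower, 1 not passing, median log2 −0.79, adjusted p = 0.000913) and rapid wound and touch responses (11 lower, 5 not passing, 15 lower adjusted over the list alone, median log2 −1.31, adjusted p = 0.00278) were lower (adjusted p = 0.498 and 0.67 with an estimated correlation). The homocysteine methyltransferase HMT3 (AT3G22740) rose 6.05-fold (228 ± 36.8 against 37.7 ± 15.3 CPM), and the dark-induced SEN1 (AT4G35770) fell 10.5-fold (1.26 ± 0.312 against 13.1 ± 5.85 CPM). The monolignol (median −0.22, adjusted p = 0.205) and wall transcription factor (−0.15, adjusted p = 0.0932) calls ended against wild-type replicates 1 to 4 alone, where 5397 genes changed, and the wound call (−0.63, adjusted p = 0.301) against 5 to 8 alone.

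The line med5a/b ref2 had the most changed genes against wild type. Glucosinolate, defence and detoxification genes rose and wall, vessel and photosynthesis genes fell. The test called 13904 genes, 6895 higher and 7009 lower, 1371 and 1801 of them by at least 2-fold. Replicates 3 and 4 differed most (chi-square per gene 81.6, against 13.03 between 1 and 2). Genes of aliphatic glucosinolates (20 higher, 1 lower, median log2 1.48, adjusted p = 1.25e-20) and indole glucosinolates (12 higher, 1 lower, 1 not passing, median log2 1.15, adjusted p = 7.92e-06) rose (adjusted p = 0.189 and 0.199 with an estimated correlation). The chain-elongation enzyme MAM1 (AT5G23010) was at 5240 ± 672 CPM against 1400 ± 179, CYP79F2 at 42.1 ± 4.05 against 4.51 ± 0.818 and CYP81F2 3.43-fold higher. Genes of salicylic acid defence (17 higher, 3 not passing, median log2 1.4, adjusted p = 0.000195) and detoxification (12 higher, 3 not passing, median log2 1.23, adjusted p = 6.16e-05) rose (adjusted p = 0.49 and 0.447 with an estimated correlation). GSTU4 rose 37.5-fold (19.1 ± 12.6 against 0.51 ± 0.282 CPM) and GSTF6 21.5-fold. Genes for secondary wall polysaccharides (19 lower, 1 not passing, median log2 −0.88, adjusted p = 0.000193) and secondary wall transcription factors (1 higher, 20 lower, 5 not passing, median log2 −0.64, adjusted p = 0.000144) fell (adjusted p = 0.645 and 0.612 with an estimated correlation). The vessel regulator VND7 (AT1G71930) fell 3.26-fold (1.66 ± 0.539 against 5.46 ± 0.715 CPM) and MYB54 3.04-fold. All 6 tracheary element death genes fell (6 lower, median log2 −1.07, adjusted p = 0.00319, adjusted p = 0.511 with an estimated correlation). Photosynthesis genes were lower (16 lower, 6 not passing, 17 lower adjusted over the list alone, median log2 −0.44, adjusted p = 0.0037, adjusted p = 0.758 with an estimated correlation). The phospholipase PLA2A (AT2G26560) (38.7 ± 18.2 against 0.454 ± 0.318 CPM, log2 6.43 ± 0.44, adjusted p = 1.55e-17) and PR4 (33.2-fold, 1440 ± 1110 against 43.4 ± 25.4 CPM) rose, and XTH18 (204-fold, 0.0497 ± 0.0287 against 11.1 ± 14.9 CPM) and LNG2 (AT3G02170) (36.3-fold, 0.971 ± 0.388 against 35.7 ± 32.7 CPM) fell. The log2 changes were 5.05 for PR4, or 4.46 without med5a/b ref2 replicate 4, and −7.68 for XTH18, or −6.87 without wild-type replicate 1. The photosynthesis call (median −0.29, adjusted p = 0.11) ended against wild-type replicates 5 to 8 alone.

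Set against med5a/b, the addition of ref2 changed 6390 genes, 3037 higher and 3353 lower, 393 and 490 of them by at least 2-fold. The defence gene HR1 (AT3G50450) (14 ± 2.78 against 0.792 ± 0.418 CPM, log2 4.15 ± 0.33, adjusted p = 1.72e-14) and ARGAH2 (16.1-fold, 46.2 ± 17.9 against 2.91 ± 1.99 CPM) were higher in med5a/b ref2, and the inositol oxygenase MIOX2 (AT2G19800) (13.9-fold, 1.06 ± 0.259 against 14.8 ± 1.7 CPM) and the Polycomb gene MEA (AT1G02580) (9.38-fold, 0.131 ± 0.0473 against 1.25 ± 0.178 CPM) were lower. Both lines shared 4547 higher and 4736 lower genes against wild type with 332 opposite, where independent lists would share 1899 and 2080. The covariance was 0.791 (r = 0.85) against a simulated 0.0178 (r = 0.32), and with wild type divided 7125 or 7665 calls were shared and 1192 or 398 opposite (r = 0.71 or 0.7).

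Between ref2 and med5a/b ref2, 12901 genes changed, 6629 higher and 6272 lower with med5a/b, 1511 and 1685 of them by at least 2-fold. Against wild-type replicates 1 to 4 and 5 to 8, ref2 gave 5397 and 10786 genes, and med5a/b ref2 13808 and 13090. The lines thus lay nearer different wild-type sets, and what divides those sets is not separated from med5a/b here. PLA2A (135-fold, 38.7 ± 18.2 against 0.283 ± 0.117 CPM) and GSTU4 (104-fold, 19.1 ± 12.6 against 0.175 ± 0.103 CPM) were higher than in ref2, and GER3 (0.211 ± 0.328 against 74.7 ± 37.2 CPM, log2 −8.27 ± 1.45, adjusted p = 3.5e-06) and XTH18 (150-fold, 0.0497 ± 0.0287 against 8.12 ± 3.04 CPM) were lower. Without med5a/b ref2 replicate 2, GER3 was at log2 −10.65. Against wild type, ref2 and med5a/b ref2 shared 1972 higher and 2092 lower genes and had 1596 opposite. Their fold changes had a covariance of 0.0593 (r = 0.11), where simulated unchanged groups gave 0.0182 (r = 0.33). With wild type divided between them the covariance was 0.0973 or −0.171, so that its sign followed the wild-type replicates used.

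An interaction term asked whether med5a/b acts alike in wild type and in ref2. It passed for 2603 genes, 1350 with a more positive effect in ref2 and 1253 with a more negative one. PYD4 (AT3G08860), an aminotransferase of pyrimidine catabolism, fell with med5a/b in wild type (log2 −1.07 ± 0.28) and rose in ref2 (3.11 ± 0.35), and LSU3 did likewise (−1.36 ± 0.33 and 2.66 ± 0.41). DFR (AT5G42800), an anthocyanin enzyme, had effects of 2.01 ± 0.6 and 5.83 ± 0.91, a difference of 3.82 ± 1.07 (adjusted p = 0.0131) that was 2.21 (adjusted p = 0.186) against wild-type replicates 1 to 4, 3.04 without wild-type replicate 6 and 4.79 without ref2 replicate 1. GER3, ESM1 (AT3G14210) and BAS (AT1G78950) had more negative effects in ref2 by −6 ± 1.75, −4.59 ± 1.16 and −4.34 ± 1.3. Without med5a/b replicate 2 these were −2.26, −3.23 and −1.31 and did not pass (adjusted p = 0.716, 0.0697 and 0.652). Without med5a/b ref2 replicate 2, GER3 and ESM1 were at −8.38 and −5.51, and GER3 was at −6.7 without wild-type replicate 4. Fitting the 4 groups alone left 1339 genes, without DFR, GER3, ESM1 and BAS, and wild-type replicates 5 to 8 alone gave 5446.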

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

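The tests of depth, of stem stage, of the wild-type sets in single lines, and of strain variant, deletion and position were chosen after the results were seen. The test of handling and the counts over other splits, except that of the wild-type sets, were chosen before.

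Of 518 sets of library values, 40 had 1 library far from the others of its group by Dixon's test, where chance gives about 1 in 20. These were 38 of 490 named-gene sets, 2 of 14 monolignol scores and 0 of 14 library totals. The scores were ref8 fah1 SmF5H replicate 3 (−0.043) and ref2 replicate 2 (−0.507). In CPM, wild-type replicate 1 stood apart for ZAT12 (29.9), WRKY40 (25.3), DIC2 (72.4), CBF1 (9.71), NCED3 (3.09), ERF109 (7.17) and XTH18 (44). Replicate 2 did so for RD29A (1110) and COR6.6 (340), and replicate 3 for VSP2 (101), VSP1 (39.7), TAT3 (30.3), PLA2A (1.19), BAM5 (73), PR1 (0.234), FLOT1 (2.24) and HMT3 (70.3). Other wild-type values were CYP81D11 in replicate 4 (0.075), TPS14 (9.03) and HCHIB (1.19) in 5 and FMO1 in 6 (0.0173). Among the lines these were LOX2 in ref3-2 replicate 2 (24.7) and ref3-3 replicate 1 (8.04), PAL1 (285) and GSTF11 (146) in pal1 pal2 replicate 1, VSP1 in its replicate 4 (238), EXPA16 (3.2) and MRD1 (2.58) in 4cl1 replicates 3 and 4. Further values were GRP3S (7.13) and MYB58 (10.2) in cse-2 replicates 1 and 2, DIC2 in fah1 replicate 4 (2.61) and ADS4 in ref8 fah1 SmF5H replicate 3 (0.0995). The med5 lines added RBCS3B (559) and RBCS2B (139) in med5a/b replicate 2, and HR1 (18.1), EXT4 (1330) and GER3 (0.7) in med5a/b ref2 replicates 3, 4 and 2. The last was GSTU4 in ref2 replicate 1 (0.329). By the interaction test the effect of med5a/b differed with ref2 in 2603 genes, by log2 4.18 for PYD4, 4.02 for LSU3, 3.82 for DFR, −6 for GER3, −4.59 for ESM1 and −4.34 for BAS.

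The first pattern is that wild-type replicates 5 to 8 had a monolignol score 0.78 above replicates 1 to 4. Sequencing depth was argued against, since the score was higher in all 16 pairs of a library of 5 to 8 with one of 1 to 4, while the former had the lower total in 8 of them. A later stem stage or another tissue makeup stays open: wall polysaccharide genes scored 0.45 higher, as it would need, but lignin polymerisation genes scored lower by −0.24 (exact permutation p = 0.0286 each), and both values had been seen before. Handling before freezing stays open: over 52 mutant libraries, deviations of the wound and monolignol scores from line means had r = 0.15 (permutation p = 0.32), rho = 0.12 (p = 0.43) and r = 0.07 without the 2 farthest, which decides neither way. Stem stage is itself biological. The labels name no group difference between the sets, so none was tested, and whether they were grown or sequenced apart is not given.

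The second pattern is the lower monolignol biosynthesis list in cse-2, fah1 and ref2, tested without CSE in cse-2 and F5H1 in fah1. In cse-2 its median went from −0.724 to −0.209 against wild-type replicates 1 to 4 and kept its call (adjusted p = 0.00697), so most of the fall went with the wild-type set, but not all of it. In fah1 and ref2 that stays open, with medians of −0.248 and −0.222 and calls that ended (adjusted p = 0.0521 and 0.205). Stem stage or tissue makeup stays open in all 3, since the score less the wall score (scaled by the ratio between the wild-type sets) was −0.21, 0.11 and −0.3 from wild type (exact permutation p = 0.0646, 0.62 and 0.0283, adjusted over 3 lines 0.0969, 0.62 and 0.0849). An effect of each lesion on the pathway stays open as the biological explanation.

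The third pattern is the crowding of genes lost in C4H:F5H. Change without regard to position was argued against by the 17 lost genes in 1 bin of 100. One deletion of adjacent genes was argued against by their spread over 10 runs, of at most 4 genes each, with genes above log2 −1 between the runs, while smaller deletions stay open. A segment from another strain, whose reads match the reference less well, would also bring genes that rose, and 3 were at least 8-fold higher in that bin (one-sided Fisher's exact p = 0.00524). A candidate explanation is therefore a strain variant against the reference; an effect of the transgene on genes near it was not tested.

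Each comparison was set against other splits of its libraries, fitted alone. In single tests chance was excluded at 5%, but not a set difference as in wild type. Exceptions were the interaction (splits mix main effects) and wild-type sets (chosen after seeing data). The real split was the only 1 of 100 to give as many genes in ref3-2 (10337, highest other 4263), ref3-3 (7947, 654), pal1 pal2 (2102, 1202), cse-2 (1093, 3), cadc cadd (8756, 1) and C4H:F5H (11355, 1). The same held for ref8 fah1 SmF5H (8127, 321), med5a/b (9474, 4774), med5a/b ref8 (9755, 767), med5a/b ref2 (12252, 4725), ref2 (6781, 1) and the interaction (1339, 1251). It was 1 of 35 for ref3-2 against ref3-3 (10259, 0), med5a/b ref8 against med5a/b (2737, 512), med5a/b ref2 against med5a/b (4301, 0) and ref2 (13057, 0), C4H:F5H against fah1 (13423, 0) and wild-type replicates 5 to 8 against 1 to 4 (6425, 0). In 4cl1, 2 of 100 splits gave as many (3887, highest other 7810). The other set wild-type replicates 5 to 8 apart, and against each set alone 4cl1 gave 3723 and 9755 genes. In fah1, 3 of 100 did (7574, highest other 8469), and both others joined fah1 replicates 1, 2 and 4 with 1 wild-type library.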

How the results depend on the processing

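Fits against wild-type replicates 5 to 8, lists without replicate 1 or 3 and wild-type sets without each library were chosen after seeing the data. All 19 counts of changed genes stayed within 1.5 times with DESeq2 size factors, DESeq2's Wald test and no filter. Of 113 list calls 113 held with DESeq2 size factors, 84 against wild-type replicates 1 to 4, 97 against 5 to 8 and 8 with an estimated correlation; without wild-type replicate 1 or 3, 218 of 226 held. Of 323 named gene results 322 held with DESeq2 size factors, 321 with the Wald test, 321 with no filter and 303 with only the groups compared. With 1 library left out, 3764 of 3804 such results held and 0 were reversed, and 50 of the 323 moved by over 1.5 times in at least 1 such fit. Genes below the filter were not tested.

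Counts moved by over 1.5 times as follows. With only the groups compared they were 2102 in pal1 pal2, 3887 in 4cl1 and 1093 in cse-2. They were 2737 in med5a/b ref8 against med5a/b and 1339 for the interaction. Such fits take the spread from those groups alone, with fewer samples. Fewer samples did not always lower a count: ref3-2 against ref3-3 gave 10259 genes fitted alone and 8389 in the shared fit. With wild-type replicates 1 to 4 they were 3723 in 4cl1, 1423 in cse-2, 7117 in fah1 and 5397 in ref2. With replicates 5 to 8 they were 6544 in ref3-3, 8337 in pal1 pal2, 7411 in cse-2 and 5446 for the interaction. The monolignol list in pal1 pal2 turned from −0.11 to 0.311 against replicates 1 to 4, and its test pointed up (median −0.07) without PAL1 and PAL2. The cause of the single changes was not tested.

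With 1 library left out, counts ran from 10567 to 11705 in ref3-2, 8674 to 10479 in ref3-3, 3160 to 5942 in pal1 pal2 and 4746 to 7370 in 4cl1. They ran from 1384 to 2962 in cse-2, 8930 to 11190 in cadc cadd and 8638 to 12274 in fah1. The range was 11360 to 12839 in C4H:F5H, 8395 to 10224 in ref8 fah1 SmF5H, 10373 to 12456 in med5a/b, 10193 to 12164 in med5a/b ref8, 12843 to 13939 in med5a/b ref2 and 7218 to 8829 in ref2. Between lines they ran from 7352 to 7687 for ref3-2 against ref3-3, 3916 to 4658 for med5a/b ref8 and 5025 to 6149 for med5a/b ref2 against med5a/b. It was 12088 to 12702 for med5a/b ref2 against ref2, 13612 to 14751 for C4H:F5H against fah1 and 1953 to 3046 for the interaction. For wild-type replicates 5 to 8 against 1 to 4 it was 2953 to 8821.

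Replicate numbers are shared between groups, but the samples share only a number. Of 52 pairs with wild type, 12 had a correlation of deviations over 0.1 (−0.513 to 0.506), and 17 of 56 libraries were closest to their own number. With the number as a replicate block, counts were 3664 in 4cl1, 1385 in cse-2, 7049 in fah1 and 5365 in ref2, near those against wild-type replicates 1 to 4, since 5 to 8 share no number with a line. In that fit 88 of 113 list calls and 302 of 323 named gene results held. The monolignol list in pal1 pal2 (0.312) and C3H1 in ref8 fah1 SmF5H (log2 0) lost their sign and call.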

Other observations

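MRD1 and its neighbour HEI10 were called lower than wild type in the same 5 lines. MRD1 stood at 31.4 CPM in wild type and at 0.299 in ref3-2, 1.11 in 4cl1, 0.308 in cse-2, 4.25 in med5a/b and 2.21 in med5a/b ref2, where HEI10 stood at 0.793, 0.79, 0.664, 2 and 1.82, against 3.81 ± 0.726 in wild type and 15.5 ± 9.4 in med5a/b ref8. QQS went either way, from 22.6 ± 8.02 CPM in wild type to 73.4 ± 5.08 in ref2 and 74.5 ± 5.83 in med5a/b ref8 and to 2.64 ± 0.627 in med5a/b ref2, 3.69 in ref3-3 and 4.44 in fah1. These levels were picked out after they were seen, and no explanation was tested.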
